A study of Mus musculus with 16 samples.

How the data were processed

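The series holds RNA of 8 mouse mammary fibroblast lines of the FVB/N strain, with 2 cultures per line and 1 array per culture. Per the labels, the lines were immortalized with the E6 gene of human papillomavirus and grown for 72 h on a gel of Matrigel and collagen I in DMEM with 10% serum. RNA was extracted with Trizol, cleaned on RNeasy columns with DNase I and checked on a Bioanalyzer, and biotin-labelled cRNA was made with the Ambion MessageAmp kit. Each line was assigned to the stage of the lesion given in its label. Whether the lines come from separate mice, and which arrays shared a chip or a labelling day, is not given in the sources used here.

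The authors deposited 2 tables. The first gives the intensity of each probe on each array on a linear scale, per the file headers without normalization, together with the detection p-value of the probe against the negative controls of the same array; the p-values step by 0.00125. The second deposited table gives an intensity on a linear scale that, by its values, the authors quantile normalized between arrays without subtracting background, since every array has the same quantiles (largest spread 0.225). The scanner software and its settings are not given in the sources used here. The first table was analysed, and the second served as an alternative.

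Intensities were background corrected, quantile normalized and log2 transformed with neqc of limma 3.58.1 in R 4.3.3 (offset 16), in which the negative control distribution is inferred from the detection p-values. Of the 25697 probes, 23978 have a gene symbol, 0 have several and 1719 have none; 23962 matched a gene of the reference by Entrez number. Probes were tested when the detection p was under 0.01 on at least 2 arrays, which left 10453 probes (40.7%), of which 9865 had a symbol and 588 none, for 7447 genes. A gene stands for its probe of highest mean over all arrays. Low intensities are compressed toward the background, so differences of dim probes are underestimated. Where all arrays of a group fell short of detection, the fold change is given as a bound, as "at least", and not at all where the bound was under 1.

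For stages, cultures were averaged per line and a linear model with 1 mean per stage was fitted in limma (lmFit, eBayes; residual degrees of freedom 4, prior 2.96), so that lines are the replicates. Hyperplasia and adenoma have 1 line each, whose spread was taken from the normal and carcinoma lines. The trend was a slope over stages numbered 0 to 3. Differences between lines used a model with 1 mean per line and cultures as replicates (residual degrees of freedom 8, prior 3.69). A probe was called apart from both normal lines when each line of the stage differed from each normal line in the same direction. The p-values were adjusted by the Benjamini-Hochberg method over all probes within each comparison, two-sided, with a threshold of 0.05. The residual spread was zero for 1 probe. A correlation between stage differences was set beside 100 simulated draws without a stage effect, because the differences share the normal lines.

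Before the data were examined, 29 gene lists with 604 genes were fixed, of which 373 were tested. They cover YAP/TAZ targets, smooth muscle contractile and SRF target genes, Cdc42 effectors and septins, focal adhesion, fibrillar matrix, basement membrane, matrix crosslinking and proteolysis, TGF-beta, CAF markers, inflammatory cytokines and chemokines, interferon response, proliferation, p53 targets, the Wnt pathway, growth factors, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein response, heat shock and HOX genes. The result of 1 further list is not reported. Lists for other cell types cover mammary epithelium, leukocytes, endothelium, adipocytes, pericytes, skeletal muscle, Schwann cells and bone or cartilage. Each list was tested against the other genes with camera (preset correlation 0.01), with the correlation estimated per list, and with fry, which tests whether the genes of a list move on balance one way. Lists in the sets apart from the normal lines were counted with Fisher's exact test, one-sided for over-representation, over the 7447 genes and adjusted over lists within each line and direction. This test takes genes as independent, so its p-values are too small for lists whose members move together.

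Named genes followed a rule fixed in advance. It takes the 10 highest and 10 lowest fold changes that passed in carcinoma against normal, and 5 of each in hyperplasia and adenoma against normal and in the trend, where the gene was detected on every array of the higher group and every line lay on one side of both normal lines. Where fewer than 5 passed in a direction, the 5 with the smallest p are named as not passing. It also takes the 5 genes of largest range among the carcinoma lines, 3 of each direction between the normal lines, up to 4 members per list by p in carcinoma against normal, and 16 genes whatever their values: Acta2, Fn1, Ccn2, Ccn1, Ankrd1, Myl9, Diaph3, Anln, Myh10, Cdc42ep3, Dkk3, Fap, S100a4, Pdgfrb, Vim and Col1a1. Genes named for carcinoma against hyperplasia, list members named for hyperplasia, adenoma and single lines, and those named in the closing section, were chosen after their values were seen.

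Alternatives changed the normalization (normexp with offset 50 and quantile normalization, quantile normalization alone, the authors' table), the detection filter (none, at least 4 arrays), the treatment of cultures (line as a random block through duplicateCorrelation with statmod 1.5.0, with and without the culture number as a block, or arrays as independent), the lines in the fit, the variance model (eBayes with an intensity trend), the threshold (adjusted p under 0.10, or a log2 difference of at least 1 besides), the probes of a gene, and left out each line or array in turn. The test was tried on simulated data with the spread of these lines: of 100 probes changed by 1 log2 unit in carcinoma, 16% were called, and 84.2% of those changed by 2. In hyperplasia the shares were 0.8% and 40.6%, and in adenoma 1.2% and 45%. Among unchanged probes, 6.2 were called on average in carcinoma, 1.4 in hyperplasia and 3 in adenoma. Because lines differ without any stage effect, 5.2, 185 and 178 unchanged probes lay apart from both normal lines, so that counts of probes apart describe lines and not stages. These are means of 5 runs in which a probe had the same spread in every line. In the data lines were unlike: the SD of the log2 difference between cultures was 0.22 in CAF1 and 0.75 in NF3. The normal lines differed in 15 probes, and CAF2 and CAF1 in 1546. The simulated counts are therefore a rough guide. A list of 20 genes shifted by 0.5 was called in 20 of 20 simulations. Genes were drawn independently there, so this cannot show how camera with the preset correlation behaves on lists whose members move together. The estimated correlation was 0.645 in the contractile and 0.672 in the interferon list. Chromosome membership and the order of genes came from the RefSeq annotation of GRCm38.p6. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.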

Results

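RNA from mouse mammary fibroblast lines was measured on 16 Illumina bead arrays. The 8 lines came from FVB/N mice and were grown in 2 cultures each, with 1 array per culture. Lines NF2 and NF3 were derived from normal mammary gland. HpAF1 came from hyperplasia, AdAF1 from adenoma, and CAF1, CAF2, CAF3 and CAF4 from carcinoma of mice that carry the polyoma middle T oncogene under a mammary promoter (MMTV-PyMT). Normal tissue was thus represented by 2 lines and 4 arrays, hyperplasia and adenoma by 1 line and 2 arrays each, and carcinoma by 4 lines and 8 arrays. Per array, between 7445 probes (NF3, culture 2) and 9823 probes (CAF3, culture 1) of the 25697 on the array gave a signal above the negative controls at a detection p under 0.01. Detected probes numbered 9600 and 7929 in the NF2 cultures, 7602 and 7445 in NF3, 7954 and 7993 in HpAF1, 9093 and 7749 in AdAF1, 9599 and 9394 in CAF1, 7748 and 8687 in CAF2, 9823 and 9236 in CAF3, and 7693 and 9204 in CAF4. The number of arrays limits the precision of every value given here.

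Across the tested probes, which are not independent replicates, cultures of one line correlated between 0.936 (NF3) and 0.994 (CAF1). Averaged over cultures, the normal lines NF2 and NF3 correlated at 0.979. The closest arrays of different lines were the first cultures of AdAF1 and CAF1, at 0.978. Cultures of NF2 correlated at 0.953, below the 0.964 between culture 2 of NF2 and culture 2 of CAF4. In NF3 and CAF4 as well, an array of another line correlated more closely than the line's own second culture.

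The comparison of carcinoma with normal lines asked which genes distinguish fibroblasts of established tumours from those of the healthy gland. Epha3, a receptor for membrane-bound ephrins in contact-dependent cell guidance, had a lower mean in all 4 carcinoma lines than in both normal lines. Its normalized log2 intensity was 7.92 in NF2 and 8.30 in NF3, against 5.48 in CAF1, 4.62 in CAF2, 4.60 in CAF3 and 4.58 in CAF4. The low level was not particular to carcinoma, as Epha3 stood at 5.36 in HpAF1, below CAF1, and at 7.11 in AdAF1. Epha3 was detected on 0 of 8 carcinoma arrays, so that its level was at least 4.04-fold lower in carcinoma than in normal lines. By a second Epha3 probe it was at least 1.15-fold lower. Each of the 8 pairs of a carcinoma and a normal line differed in Epha3 when cultures served as replicates, and this was the 1 probe of 10453 for which that held. In simulations that gave every line the same spread, 5.2 unchanged probes met that criterion on average. In that setting, 1 probe is no more than differences between lines give.

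With lines as the replicates (4 against 2), 0 probes passed an adjusted p of 0.05 in limma, and 7 did with arrays taken as independent. The lowest adjusted p was 0.151, for Epha3. At an unadjusted p under 0.05 there were 293 probes, 2.80% of those tested, of which 156 were higher and 137 lower in carcinoma. Because no gene passed, the 5 with the smallest p in each direction are given as not passing. On the higher side these were Fam199x at 0.70 (SE 0.16), Sema5a, a semaphorin of axon guidance, at 1.06 (SE 0.26), Fabp3, a fatty acid carrier, at 1.09 (SE 0.26), Ska3, a kinetochore protein, for which no fold is given as it was detected on 0 normal arrays, and Etv4, an ETS transcription factor, at 1.19 (SE 0.32). On the lower side, Epha3 was followed by Rspo3, a secreted amplifier of Wnt signalling, which was at least 1.39-fold lower. The others were Kcne4, a potassium channel subunit, at -2.08 (SE 0.37), Gper1, a membrane receptor for oestrogen, at -0.92 (SE 0.19), and Ssh3, a cofilin phosphatase, at -1.31 (SE 0.26). Epha3 passed over lines when CAF1 was left out, and over arrays with the line as a random block, with or without the culture number as a block. Without either CAF1 culture 0 probes were apart from both normal lines in all pairs.

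Smooth muscle contractile genes and targets of serum response factor (SRF), the transcription factor of the contractile cytoskeleton, lay higher in carcinoma than in normal lines as a group. All 19 tested members had a higher mean, with a median log2 difference of 0.51. Cnn2, an actin-binding calponin, stood at 0.85 (SE 0.31), Myh9, the heavy chain of non-muscle myosin, at 0.34 (SE 0.20) and Lmod1, an actin nucleator of smooth muscle, at 0.74 (SE 0.45). Acta2, the alpha smooth muscle actin used as the marker of contractile myofibroblasts, differed by 0.52 (SE 0.21, unadjusted p = 0.0441, adjusted p = 1). This Acta2 probe lay at the top of the intensity range, up to 15.84, so its difference may be compressed. The other Acta2 probes, which lie further from that top, gave 1.51, 1.02 and 1.28. The list differed from the other genes in camera (adjusted p = 1.38e-05), but not when the correlation between its genes was estimated (adjusted p = 0.768 with an estimated correlation). In it, 0 members passed over all genes tested and 0 adjusted over the list alone.

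**Figure D1:**
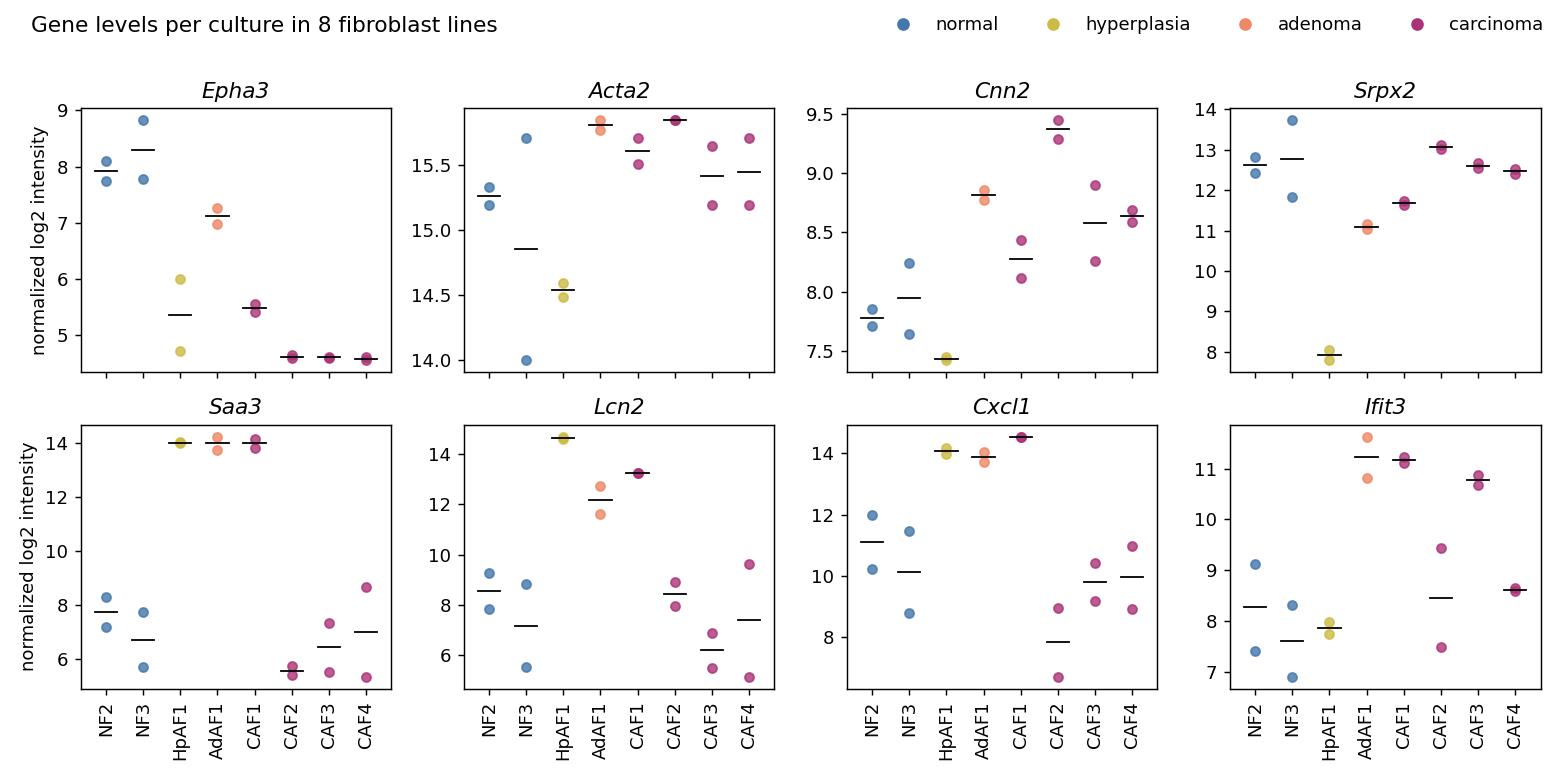
Normalized log2 intensity (vertical axis) of 8 genes in the 8 lines (horizontal axis); each point is 1 culture, black lines are line means and colours give the stage. By line means, Epha3 lies between 7.92 and 8.30 in the normal lines, at most at 5.48 in the carcinoma lines and at 5.36 in HpAF1. Saa3 lies between 13.98 and 14.00 in HpAF1, AdAF1 and CAF1 and at most at 7.74 in the other lines.

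Interferon response genes were also higher as a group: 21 of 23 tested members had a higher mean in carcinoma, with a median of 0.58. B2m, the light chain of MHC class I, stood at 0.42 (SE 0.18), Ifit3 at 1.81 (SE 0.83) and Ifit2 at 0.64 (SE 0.34), the latter being interferon-induced inhibitors of viral translation, and Stat2, which carries the interferon signal to the nucleus, at 0.46 (SE 0.25). Camera gave an adjusted p = 2.76e-05, and an adjusted p = 0.768 with an estimated correlation. Without CAF1 the adjusted p was 0.184. HOX genes, which record the position of a cell along the body axis, were lower: 12 of 16 members had a lower mean, with a median of -0.44, and Hoxa5 stood at -0.90 (SE 0.43), Hoxb6 at -0.54 (SE 0.27), Hoxb7 at -0.51 (SE 0.25) and Hoxa7 at -0.55 (SE 0.32). The adjusted p was 0.0445 in camera and the adjusted p = 0.768 with an estimated correlation. It was 0.0566 with the authors' normalized values, 0.311 without NF2, 0.330 without CAF1 and 0.0905 without CAF3. In either list, 0 members passed over all genes tested or adjusted over the list alone.

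Targets of YAP and TAZ, the transcriptional co-activators that respond to tension in the matrix, had a higher mean in carcinoma for 12 of 16 members, and the list did not pass (adjusted p = 0.108). Ccn2 stood at 0.51 (SE 0.39), Ccn1 at 0.71 (SE 0.38), Ankrd1 at 1.09 (SE 1.16), Gadd45a at 1.00 (SE 0.60) and Fjx1 at 0.53 (SE 0.43). Diaph3, a formin that builds actin filaments, stood at 0.51 (SE 0.29), Anln, an actin-binding protein of cytokinesis, at 0.57 (SE 0.34), Myh10, a non-muscle myosin, at 0.30 (SE 0.35) and Cdc42ep3, an effector of Cdc42, at 1.17 (SE 0.56). Dkk3, a secreted relative of the Dickkopf Wnt inhibitors, stood at 1.19 (SE 0.88). The fibroblast markers S100a4 at -0.26 (SE 0.27), Pdgfrb at -0.47 (SE 0.33), Vim at 0.17 (SE 0.35) and Col1a1 at 0.04 (SE 0.27) all lay within 2 SE of 0. Fn1 and Myl9 have no probe under their name, and Fap, detected on 0 arrays, was not tested.

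The other lists did not pass in this comparison. The basement membrane (9 of 11 members lower, Col4a5 at -0.66 with SE 0.22), matrix crosslinking and proteolysis (18 of 26 lower, Loxl4 at -0.75 with SE 0.18) and mammary epithelium (3 of 3 higher) each had an adjusted p of 0.108. Proliferation (15 of 20 higher), the Wnt pathway (7 of 14 lower), skeletal muscle (2 of 3 higher) and Schwann cell and neural crest genes (2 of 2 higher) had 0.262. In the Wnt list, 1 gene passed adjusted over the list alone, Rspo3. Focal adhesion (13 of 16 higher) had 0.510, Cdc42 effectors and septins (6 of 9 lower) and TGF-beta genes (10 of 17 higher) had 0.527, and p53 targets (11 of 16 higher), heat shock (7 of 10 higher) and pericyte markers (4 of 5 higher) had 0.551. CAF markers (8 of 13 higher) had 0.613. Growth factors (10 of 18 higher), hypoxia and glycolysis (10 of 17 higher), macrophage and leukocyte (3 of 5 lower) and bone and cartilage genes (2 of 4 lower) had 0.743. The inflammatory list had 0.871, with 13 of 22 members higher. Adipocyte genes (4 of 6 lower) had 0.971. Fibrillar matrix (11 of 17 higher, Col3a1 at -1.13 with SE 0.31), cholesterol synthesis (7 of 13 higher), the unfolded protein response (9 of 14 lower) and endothelium (3 of 5 higher) had 0.988. Signs were mixed for the inflammatory list (median 0.31, mean -0.04) and growth factors (median 0.06, mean -0.11), both tested as higher. The same held for cholesterol synthesis (median 0.02, mean -0.02) and bone and cartilage (median 0.06, mean -0.02), tested as lower, and for the unfolded protein response (median -0.03, mean 0.05), tested as higher. Cdc42 effectors (median -0.14, mean 0.01) were tested as lower, and leukocyte genes (median -0.07, mean 0.02) likewise.

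The comparison of hyperplasia with normal asked what sets apart the fibroblasts of the earliest lesion, represented by 1 line. An effect of stage cannot be told apart from one of that line or of its handling. HpAF1 lay apart from both normal lines in more probes than any of the other lesion lines. Nt5e, the ectoenzyme CD73 that makes adenosine and that is also on the YAP/TAZ list, rose by a log2 difference of 5.05 (SE 0.64, adjusted p = 0.0384), and Upk3b, a uroplakin, rose at least 6.98-fold. Cadm1, an immunoglobulin adhesion molecule, rose at least 8.29-fold, Cxadr, the tight junction receptor for coxsackievirus and adenovirus, at least 5.24-fold, and Slco4a1, an organic anion transporter, at least 5.52-fold. Srpx2, a secreted sushi-repeat protein, fell by 4.79 (SE 0.51, adjusted p = 0.0207), Ctsh, a lysosomal cathepsin, fell by 2.71 (SE 0.25, adjusted p = 0.0128), and Kdelr3, a receptor that returns proteins to the endoplasmic reticulum, fell by 2.03 (SE 0.24, adjusted p = 0.0301). Efs, a docking protein of Src kinases, fell at least 6.63-fold, and Chst1, a keratan sulfate sulfotransferase, at least 5.08-fold. The adjusted p of these 10 genes lay between 0.00361 and 0.0488.

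In limma, 34 probes of 25 named genes passed, 26 higher and 8 lower in hyperplasia; the lone line was assumed to vary like the lines of the other stages. Of the 34, 19 were detected in HpAF1 alone, and with detection required on at least 4 arrays 0 passed. The median residual SD of the 34 was 0.162, against 0.278 over all tested probes; a spread that small, as signals near background have, makes a call easier. The count was 0 without NF3, 3 without NF2, 13 without CAF3, 16 without CAF4 and 82 without CAF1. It was 256 with the line as a random block, 217 with the culture number as a further block, 258 with only the 2 groups in the fit and 780 with arrays as independent. Without the detection filter it was 52, with normexp scaling 21 and at an adjusted p under 0.10 it was 73. When cultures served as replicates, HpAF1 lay apart from both normal lines in 804 probes, 445 higher and 359 lower, against 185 unchanged probes on average in simulations. Without culture 1 or 2 of HpAF1 the count fell to 294 and 253. Of the higher ones, 100 and 34 were on chromosomes 6 and 18. Of the 34 probes that passed over lines, 1 was on each of these chromosomes. Chromosome membership and gene order came from the RefSeq annotation of GRCm38.p6, since the build of the array is not given in the sources used here. P-values between cultures measure the spread of these cultures only, which can be technical.

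Saa3 and Lcn2 headed the genes that were higher in HpAF1 than in both normal lines. The 8 furthest from the nearer normal line in each direction were named under a rule added after the data were seen. The differences printed are from the mean of the normal lines, by which the ranking is another. Saa3, an acute-phase serum amyloid, differed from the normal mean by 6.77, Lcn2, an iron-sequestering lipocalin, by 6.81, and Clu, a secreted chaperone, by 5.70. Bmp4, a morphogen of the TGF-beta family, differed by 5.68, Mfap4, a microfibril protein, by 5.04, Mdk, the growth factor midkine, by 4.95 and Chil1, a chitinase-like lectin, by 4.91; Nt5e was also among them. On the lower side stood Srpx2, Galnt9, a GalNAc transferase of mucin-type glycosylation (at least 6.75-fold lower), Ly6c1 (-4.50), Mustn1 (-4.07), Il1rn, the interleukin-1 receptor antagonist (at least 10.7-fold lower), Pla1a, a phospholipase (-4.49), Sncg, gamma-synuclein (at least 8.20-fold lower, with a second probe not detected in either group), and Brinp3 (at least 5.39-fold lower). Over lines, Saa3 (SE 3.13, adjusted p = 0.446) and Lcn2 (SE 2.55, adjusted p = 0.362) did not pass.

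Of the lists, cholesterol synthesis was lower in hyperplasia, with 11 of 13 members below the normal mean and a median of -0.51. Hmgcs1, which starts the pathway, stood at -1.37 (SE 0.25), Nsdhl at -1.27 (SE 0.32) and Sqle, the squalene epoxidase, at -0.82 (SE 0.25). The adjusted p was 0.00730, and the adjusted p = 0.502 with an estimated correlation; 0 members passed over all genes tested and 2 adjusted over the list alone. Growth factors were higher (15 of 18 members, median 0.71, adjusted p = 0.0237, and adjusted p = 0.502 with an estimated correlation), with Bmp4 and Vegfc, a lymphatic growth factor (3.38, SE 1.16), among them. For them, 0 passed over all genes tested and 1 adjusted over the list alone. Growth factors lost the call without NF3 (adjusted p = 0.0753).

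In the fibrillar and the crosslinking list most tested members had a lower mean in HpAF1, but single members rose strongly. Mmp3, Mmp10 and Mmp13 of the crosslinking list and Dcn of the fibrillar list were higher than in both normal lines. Mmp3 stood 5.08 above the normal mean, and the crosslinking list had a mean of -0.10 against a median of -0.60. In fibrillar matrix, 11 of 17 members lay below the normal mean (median -0.68, adjusted p = 0.0415, and adjusted p = 0.502 with an estimated correlation), with Sparc, a collagen-binding glycoprotein, at -1.32 (SE 0.28), Mfap5 at -2.10 (SE 0.46), Col3a1 at -1.82 (SE 0.45) and Col1a1 at -1.26 (SE 0.38). In matrix crosslinking and proteolysis, 17 of 26 did (median -0.60, adjusted p = 0.0406, and adjusted p = 0.502 with an estimated correlation), with Mmp23 at -1.84 (SE 0.26), the lysyl oxidases Loxl1 at -1.42 (SE 0.29) and Lox at -1.52 (SE 0.46), and Mmp10, a stromelysin, at least 9.00-fold higher. In each list 0 members passed over all genes tested and 3 adjusted over the list alone. Contractile and SRF genes were lower too (16 of 19, median -0.52, adjusted p = 0.0406, and adjusted p = 0.892 with an estimated correlation), with Myh9 at -1.05 (SE 0.29) and Tpm2, a tropomyosin, at -1.42 (SE 0.59). In that list 0 members passed by either adjustment. With all probes of a gene averaged, the contractile, fibrillar and crosslinking lists had adjusted p of 0.0669, 0.0758 and 0.0540, and without NF2 0.158, 0.10 and 0.161. The fibrillar list also lost its call without NF3 (0.0574), CAF2 (0.0756) or CAF4 (0.0513), and crosslinking without CAF2 (0.0756), with normexp scaling (0.0609) and with the authors' values (0.0852).

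Single members stood out in lists that did not pass in hyperplasia. Of the YAP/TAZ targets, Nt5e rose over all genes tested, and 2 members passed adjusted over the list alone; the list itself had 7 of 16 members higher (adjusted p = 0.931). Of the Wnt list, Rspo3 rose by 3.03 (SE 0.31, adjusted p = 0.0206). The interferon list had 15 of 23 members lower (adjusted p = 0.931) and the inflammatory list 15 of 22 higher (adjusted p = 0.30). The other 19 lists had adjusted p-values between 0.218 and 0.980. Median and mean differed in sign for the YAP/TAZ, TGF-beta, unfolded protein response, leukocyte and pericyte lists, and focal adhesion was tested as higher with both below 0. Counted among the named genes of the set apart from both normal lines, with Fisher's exact test over the 7447 genes tested, the inflammatory list was over-represented on the higher side. It held 6 of 22 members there (Cxcl5, Lcn2, Nfkbia, Nfkbiz, Ptges and Saa3) where 0.954 were expected (adjusted p = 0.00762). The test takes genes as independent, while the estimated correlation within this list was 0.589, so that p-value overstates the evidence. On the lower side there were 7 of 26 crosslinking genes (Adam12, Lox, Loxl1, Loxl2, Mmp23, P4ha2 and Plod1; adjusted p = 0.000785) and 4 of 16 YAP/TAZ targets (Ccn2, Fjx1, Nuak2 and Tgfb2; adjusted p = 0.0312). The higher side held 3 crosslinking genes (Mmp3, Mmp10 and Mmp13) and 2 YAP/TAZ targets (Nt5e and Ptpn14), neither over-represented (Fisher's exact test, adjusted p = 0.721 for each).

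The comparison of adenoma with normal asked the same of the next stage, again with 1 line, AdAF1. Here too, stage cannot be told apart from the line or its handling. Interferon response and inflammatory genes were higher as groups. All 23 tested interferon members had a higher mean (median 0.87), with Ifit3 at 3.28 (SE 1.18), Isg15, a ubiquitin-like modifier, at 3.90 (SE 1.67), Usp18, which removes it, at 3.99 (SE 1.84) and Rsad2, the antiviral enzyme viperin, at least 1.86-fold higher. Of the inflammatory list, 19 of 22 members had a higher mean (median 1.57), with Nfkbia, the inhibitor of NF-kappa-B, at 1.62 (SE 0.42), Saa3 at 6.74 (SE 3.13), and the chemokine Cxcl10 at least 2.74-fold higher, while Il1rn was at least 12.3-fold lower. The adjusted p was 3.66e-09 for the interferon and 1.35e-05 for the inflammatory list, and for each of them the adjusted p = 0.637 with an estimated correlation. In both lists, 0 members passed over all genes tested and 0 adjusted over the list alone.

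Contractile and SRF genes (18 of 19 higher, median 0.45, adjusted p = 0.00148), YAP/TAZ targets (11 of 16, median 0.63, adjusted p = 0.0240), focal adhesion (13 of 16, median 0.33, adjusted p = 0.0293) and hypoxia and glycolysis (14 of 17, median 0.40, adjusted p = 0.0479) were higher in AdAF1. For each of these 4 lists the adjusted p = 0.637 with an estimated correlation. Tagln, the smooth muscle marker transgelin, stood at 1.98 (SE 0.96), Tpm1, a tropomyosin, at 1.09 (SE 0.48), and Ccn1, a matricellular YAP target, at 1.62 (SE 0.54), while Egln1, an oxygen sensor, was higher without a fold, being detected on 0 normal arrays. Cholesterol synthesis was lower (11 of 13, median -0.17, adjusted p = 0.0372, and adjusted p = 0.637 with an estimated correlation), with Hmgcs1 at -0.66 (SE 0.25). Bone and cartilage genes were lower (4 of 4, adjusted p = 0.0415), with Sox9, the regulator of cartilage formation, at least 1.53-fold lower, and the 3 tested members of the mammary epithelial list were higher (adjusted p = 0.0415), with Gata3 detected on 0 normal arrays and 1 AdAF1 array; the other 19 of its 22 genes were not detected or had no probe. For these last 2 lists the adjusted p = 0.637 with an estimated correlation. In each of the 7 lists 0 members passed over all genes tested and, adjusted over the list alone, 1 passed in bone and cartilage and 0 in the others. Without NF3, only the contractile, interferon and inflammatory lists passed. The hypoxia, epithelial and bone lists did not pass with normexp scaling (adjusted p = 0.0591, 0.0630 and 0.0610) or with the authors' values (0.0647, 0.0938 and 0.0797), and hypoxia did not with all probes of a gene averaged (0.0631) or without CAF4 (0.0749). The epithelial and bone lists also lost their call without NF2 (0.0551 and 0.0714), and without CAF1 the focal adhesion, epithelial and bone lists each had 0.0512. The other 19 lists had adjusted p-values between 0.112 and 0.936; median and mean differed in sign for Cdc42 effectors, fibrillar matrix, crosslinking, Wnt and leukocyte genes.

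For single genes in adenoma, 0 probes passed in limma, or 2 with only the 2 groups in the fit; 422 had an unadjusted p under 0.05, 222 higher and 200 lower. The 5 with the smallest p in each direction, none of which passed, were Fabp3 at 1.87 (SE 0.37), Selenow, a selenoprotein, at 1.72 (SE 0.35), Mid1ip1, a regulator of fatty acid synthesis, at 1.24 (SE 0.25), Creb5, at least 3.88-fold higher, and P4ha3, a collagen prolyl hydroxylase, at 1.63 (SE 0.38). The lower ones were Kcne4 (at least 2.97-fold), Faap100, of the Fanconi anaemia DNA repair complex, at -1.40 (SE 0.27), Abhd14b at -1.39 (SE 0.30), Gper1, which was detected on 0 AdAF1 arrays and has no fold, and Tgfbi, a TGF-beta induced matrix protein, at -1.84 (SE 0.42).

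With cultures as replicates, AdAF1 lay apart from both normal lines in 137 probes, 105 higher and 32 lower. This is fewer than the 178 unchanged probes that lay apart on average in simulations, so the set can come from differences between lines alone. The simulations gave every line the same spread, which the lines here did not have. Without single arrays the count fell to 50 and 52 (AdAF1 cultures), 85 (each CAF1 culture) and 90 (each HpAF1 culture). The 8 furthest from the nearer normal line in each direction, again by the added rule, began with Saa3, Igfbp2, a carrier of insulin-like growth factors (6.26), Lrrc15, a membrane protein of activated fibroblasts (4.97), Greb1, an oestrogen-responsive gene (at least 9.34-fold), and Gpc3, a glypican (4.27). Bnc1, a zinc finger protein, was at least 5.24-fold higher, Creb5 at least 3.88-fold and Acsl6, which activates fatty acids, at least 4.00-fold. Lower were Galnt9 (at least 7.77-fold), Il1rn, Kcne4, Plxna2, a semaphorin receptor (-2.61), Gldc, the glycine decarboxylase (-2.48), Tgfbi, Pparg, the regulator of fat cell formation (-1.82), and Chst2 (-1.84). In this set, 7 of 22 inflammatory genes (Ccl2, Cxcl10, Cxcl5, Lif, Nfkbia, Nfkbiz and Saa3; adjusted p = 7.78e-08) and 3 of 23 interferon genes (Ifit3, Mx2 and Rsad2; adjusted p = 0.0302) were over-represented in Fisher's exact test. The test takes genes as independent, but the estimated correlation was 0.589 within the inflammatory and 0.672 within the interferon list. These p-values therefore overstate the evidence.

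Carcinoma was also compared with each earlier lesion, to ask what separates the stages. Against HpAF1, 44 probes of 36 named genes passed, 12 higher and 32 lower in carcinoma. Genes chosen after their values were seen serve as examples here. Chst1 rose at least 10.1-fold (adjusted p = 0.00724) and Csrp2, a LIM protein of smooth muscle, rose by 2.85 (SE 0.38, adjusted p = 0.0473), while Aldh3a1, an aldehyde dehydrogenase, fell by 4.42 (SE 0.62, adjusted p = 0.0473) and Mmp13, an interstitial collagenase, fell by 1.92 (SE 0.23, adjusted p = 0.0262; a second probe gave -4.79, adjusted p = 0.287). With detection on at least 4 arrays 7 passed; the count was 20 without each of NF2, NF3 and CAF4, 27 without CAF3, 28 without culture 1 of NF3 and 186 without CAF1. It was 390 with the line as a random block, 325 with the culture number as a further block, 1127 with arrays as independent, 20 with only the 2 groups in the fit, 72 without the detection filter and 119 at an adjusted p under 0.10. Against AdAF1, 0 probes passed in limma, with 231 at an unadjusted p under 0.05 (132 higher, 99 lower), and 16 passed without CAF1. A trend over the stages, numbered 0 for normal, 1 for hyperplasia, 2 for adenoma and 3 for carcinoma, passed in 0 probes; 304 had an unadjusted p under 0.05, 161 with a positive and 143 with a negative slope. On the rising side the smallest p belonged to Sema5a (slope 0.33, SE 0.08), Ska3, Mycl, a MYC family gene, Tab2 (0.21, SE 0.06) and Dnaaf2. On the falling side it belonged to Ssh3 (-0.48, SE 0.10), Gldc (-0.77, SE 0.16), Epha3, Kcne4 (-0.74, SE 0.17) and Rnf182 (-0.23, SE 0.06). None of these passed. Where 1 end of the trend was detected on 0 arrays (Ska3, Mycl, Dnaaf2 and Epha3) no slope is given. Epha3 did not fall stage by stage, as HpAF1 (5.36) lay below AdAF1 (7.11).

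The 3 stage differences share the normal lines, which alone makes them correlate across genes. Hyperplasia and adenoma differences correlated at 0.466 across probes, against 0.333 when no stage effect was simulated, and at 0.30 and 0.346 when each stage was given its own normal line. Adenoma and carcinoma correlated at 0.535 against 0.474 simulated, and at 0.271 and 0.222 with separate normal lines. For hyperplasia and carcinoma the values were 0.219 against 0.471, and 0.0425 and 0.0344.

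The carcinoma lines were compared with each other to ask how alike fibroblasts of one stage are. They differed in 1840 probes of 1495 named genes, 17.6% of those tested. Saa3 ranged from 5.58 in CAF2 to 13.98 in CAF1. Mmp3, a stromelysin that degrades matrix, ranged from 4.73 in CAF2 to 12.30 in CAF1, Lcn2 from 6.17 in CAF3 to 13.27 in CAF1, Cyp7b1, an oxysterol hydroxylase, from 4.87 in CAF2 to 11.94 in CAF1, and Cxcl1, a neutrophil chemokine, from 7.84 in CAF2 to 14.54 in CAF1. Saa3, Mmp3 and Cyp7b1 were detected on 0 CAF2 arrays. The adjusted p-values of these 5 genes ran from 0.000276 to 0.0101 in limma. Without either culture of CAF1 the count was 820 (culture 1) or 775 (culture 2). Pairs of carcinoma lines differed in 316 (CAF4 and CAF3) to 1546 probes (CAF2 and CAF1), while CAF1 differed from AdAF1 in 27. Among the pairs without CAF1, CAF4 and CAF2 differed in 334 and CAF3 and CAF2 in 836. A handling batch of HpAF1, AdAF1 and CAF1, taken up below, cannot be told apart from the lines. It would enter each count that involves CAF1, so these counts need not measure biological differences.

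**Figure D2:**
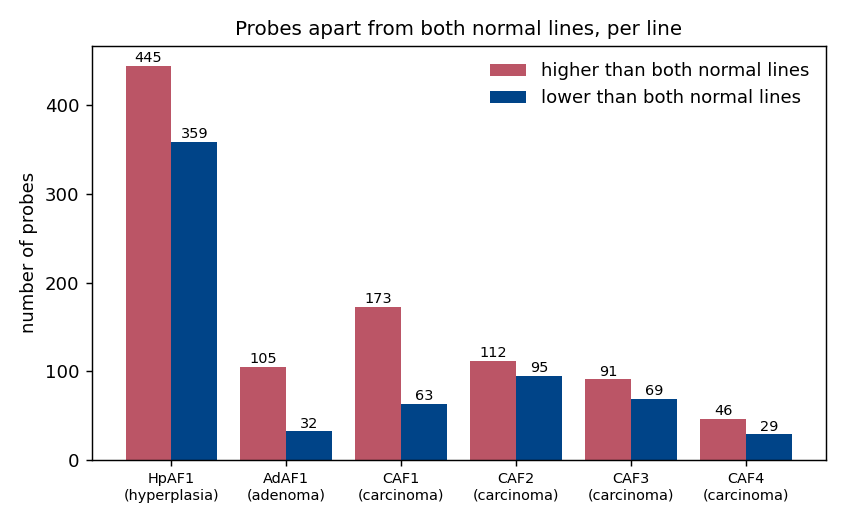
Number of probes (vertical axis) higher (left bars) or lower (right bars) than in both normal lines, for each line of a lesion (horizontal axis), with cultures as replicates. HpAF1 had 445 higher and 359 lower, and the carcinoma lines between 46 and 173 higher and between 29 and 95 lower.

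The carcinoma lines shared few of the genes in which they lay apart from the normal lines. CAF1 lay apart in 173 higher and 63 lower probes, CAF2 in 112 and 95, CAF3 in 91 and 69, and CAF4 in 46 and 29. With each array left out in turn, these totals ran from 67 to 309 in CAF1, 75 to 338 in CAF2, 51 to 232 in CAF3 and 46 to 94 in CAF4, and the sharing below was not counted again. No simulation was run for single carcinoma lines. For the single lines of adenoma and hyperplasia, simulations gave 178 and 185 unchanged probes apart, so counts of that size can come from differences between lines alone. The totals of CAF1 (236) and CAF2 (207) lay above these values, and those of CAF3 (160) and CAF4 (75) below. Of the probes apart in any carcinoma line, 368 higher and 216 lower ones were so in 1 line, 50 and 32 in 2, 4 and 7 in 3, and 0 and 1 in all 4. Inflammatory (10 of 22, adjusted p = 3.45e-11) and interferon genes (10 of 23, adjusted p = 3.45e-11) were over-represented on the higher side of CAF1 in Fisher's exact test. They included Il6, Ccl2 and Ccl5, and Irf7, Isg15 and Mx2. Fisher's exact test takes genes as independent, but the estimated correlation was 0.589 between inflammatory, 0.672 between interferon and 0.645 between contractile genes. Its p-values for these lists therefore overstate the evidence. Contractile genes (7 of 19, adjusted p = 2.79e-08) and pericyte markers (Cspg4, Mcam and Notch3, 3 of 5 tested, adjusted p = 0.000212) were over-represented on the higher side of CAF2 in Fisher's exact test. Of the 10 listed pericyte genes, Rgs5, Kcnj8, Abcc9, Des and Higd1b fell short of detection on at least 2 arrays and were not tested. In CAF2, Actg2, the smooth muscle gamma actin, had a log2 intensity of 12.33 against 8.36 and 8.11 in the normal lines, and Myh11, smooth muscle myosin, 8.21 against 4.71 and 4.77. In CAF4, 2 of 16 HOX genes were on the lower side (adjusted p = 0.0257): Hoxc6 at 8.55 against 12.01 and 12.03, and Hoxc9 at 6.95 against 10.33 and 10.36.

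The normal lines were compared to see how far controls differ. They differed in 15 probes of 12 named genes, 1 higher and 14 lower in NF3. Susd2, a sushi-domain membrane protein, stood at 7.35 in NF3 and 5.52 in NF2 (adjusted p = 0.00428). Cxcl14, a chemokine of epithelia and fibroblasts, stood at 4.89 against 9.79 (adjusted p = 0.000258), Smoc1, a basement membrane protein, at 5.71 against 9.50 (adjusted p = 0.0427), and Hspb2, a small heat shock protein, at 5.10 against 7.59 (adjusted p = 0.000107). The count was 51 and 28 without culture 1 or 2 of NF2, 158 and 43 without culture 1 or 2 of NF3, and 8 without any single array of HpAF1 or CAF1. It was 9 with normexp scaling and 24 at an adjusted p under 0.10.

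**Figure D3:**
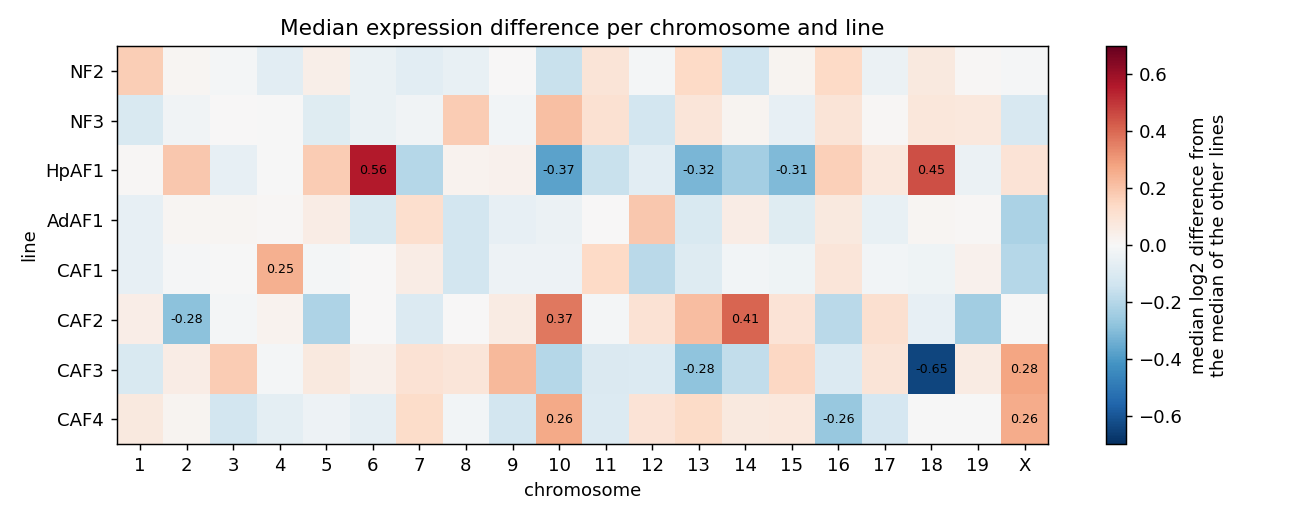
Median log2 difference of the expressed probes of each chromosome (horizontal axis) in each line (vertical axis) from the median of the other lines; colour gives the value in log2 units and values of at least 0.25 in size are written. Chromosome 18 in CAF3 (-0.65) and chromosome 6 in HpAF1 (0.56) have the largest values.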

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

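The tests that weigh the 3 patterns below were chosen only after the results they measure had been seen.

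In 5 lines, whole chromosomes lay above or below the other lines: of 160 medians over 5636 expressed probes, 15 were at least 0.25 in size, led by chromosome 18 in CAF3 (-0.65, 144 probes), chromosomes 6 (0.56, 312 probes) and 18 (0.45) in HpAF1 and chromosome 14 in CAF2 (0.41). Strain variants under single probes would shift single probes, yet at least 74.9% of the expressed probes of each of the 15 chromosomes lay on the shifted side. Under the other scalings the smallest of the 15 medians was still 0.201 in the direction of its shift, so the background step does not account for the shifts. All these scalings are quantile normalized between arrays, so they cannot decide whether that normalization plays a part. A candidate explanation is gain or loss of whole chromosomes: in 15 of the 15, all 5 gene-ordered segments and both cultures shifted the same way, where 1 extra copy beside 2 would give 0.585 and 1 lost copy -1. The negative medians ran from -0.65 to -0.26 and the positive ones from 0.25 to 0.56, all smaller in size than that. Choosing chromosomes by the size of their median also favours agreement of segments and cultures. In the normal line NF3, single cultures reached 0.46 (chromosome 8, culture 1) and 0.47 (chromosome 10, culture 2). The other culture stood at -0.10 and -0.08, so the line medians of 0.18 and 0.21 stayed under 0.25. Shifts of this size thus also occurred in 1 culture of a line and not the other. No DNA was measured, and whether stage or culture relates to these shifts was not tested.

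In HpAF1, AdAF1 and CAF1, 5 of 22 inflammatory genes lay over 1 log2 unit above every other line: Saa3, Lcn2, Cxcl1, Nfkbiz and Cxcl5, with Saa3 75.4-fold above the highest other line, where the highest of the other ways to take 3 lines (56 in all) gave 1 gene; over all tested probes 37 lay so, against at most 12 for another 3 lines, and most were not on the list, such as Bnc1, Ch25h, Acsl6, Gch1 and Npy1r. Leukocytes in the cultures are argued against by Ptprc, Tyrobp, Fcer1g, Laptm5 and Cd74, abundant leukocyte transcripts with 0 detections over the 6 arrays of these lines; of 18 listed markers with a probe, 4 were detected there (Lyz1, Lyz2, C1qa and Cd14), and Cd14 moved with the pattern (8.58, 7.70 and 7.67 against at most 6.89 in the other lines). A separate handling batch of the 3 lines cannot be told apart from the lines themselves, since the labels give no batch. The lowest correlation between cultures of these lines was 0.982, above the highest of the other lines, 0.975. Cultures of the same number deviated together, with correlations above 0.1, in 10 of 10 pairs of the other 5 lines. With HpAF1, AdAF1 or CAF1 this held in 2 of 18 pairs. The 3 include the only hyperplasia and adenoma lines and neither normal line, so such a batch would also enter those comparisons. Through CAF1 it would enter the comparisons among the carcinoma lines, and of carcinoma with other stages, as well. Stage alone does not separate the 3 lines, as CAF2, CAF3 and CAF4 share a stage with CAF1 and lack the pattern. What stays open is a difference between the lines, which may be biological or come from handling.

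In CAF3 and CAF4, 22 probes were higher than in both normal lines and 7 lower, where 0.40 and 0.191 would be expected of independent sets, although both lines were compared with the same normal lines. Of the 19 higher ones with a chromosome, 9 were on chromosome 1 (Mff, Ugt1a6a, Cops8, Ramp1, Thap4, Insig2, Mcm6, Csrp1 and Phlda3), 3 on 17 (Glo1, H2-K1 and H2-T23), 3 on 19 (Cfl1, Hps1 and Arl3), 2 on 7 and 2 on 16 (Lrrc15 and Sim2), and 12 of the 22 were undetected in the other lines, such as Csrp1 at 9.65 and 9.90 against at most 5.16. A gained chromosome is argued against by the medians of these chromosomes in both lines, of which the highest was 0.131. A shared stretch of another strain's genome, with variants that change how probes bind or which genes are active, is a candidate explanation: 19 pairs of the set were neighbours within 50 tested probes, against a mean of 1.65 and a highest value of 12 in 10000 random sets (permutation p = 1e-04, the smallest they can give; adjusted p = 0.0012 over 24 sets). The set was found and tested on the same data, 2 other sets passed this test as well (lower in HpAF1 and CAF3, higher in AdAF1 and CAF1), and a second H2-K1 probe was detected on 0 arrays.

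Among the 4 carcinoma lines, 21 of 173 named genes had 1 line far from the other 3 by Dixon's criterion. Chance meets it in about 1 in 20 groups, but that rate does not apply to this set, since some of the genes were named for their large range among these lines or their level in related lines. For Epha3 and Slco4a1, 0 carcinoma arrays were above background, so their ranking is one of undetected signals, and Loxl4 was detected on 1. CAF1 was the distant line in 13 genes. Its log2 intensity was above the range of the others for Epha3 (5.48 against 4.58 to 4.62), Nt5e (7.44 against 5.92 to 6.07), Slco4a1 (5.22 against 4.41 to 4.51), Saa3 (13.98 against 5.58 to 7.01) and Mdk (12.80 against 6.78 to 7.47). The same held for Igfbp2 (8.92 against 4.93 to 5.48), Gpc3 (8.18 against 4.84 to 4.92), Bnc1 (8.67 against 4.89 to 5.08), Csf1 (9.65 against 9.39 to 9.43) and Ngfr (6.70 against 4.87 to 4.99). It was below the range for Vim (12.76 against 13.72 to 13.91), Pdgfc (6.41 against 7.03 to 7.11) and Egln1 (5.68 against 6.08 to 6.16). CAF2 was distant in 5 genes: higher for Hoxa5 (10.34 against 9.02 to 9.18) and Adipoq (7.59 against 5.09 to 5.43), and lower for Has2 (5.81 against 7.46 to 7.53), B2m (12.98 against 13.27 to 13.32) and Alpl (5.08 against 6.74 to 6.80). CAF4 was distant in 3 genes: higher for Loxl4 (5.73 against 5.48 to 5.52), and lower for Hspb2 (4.94 against 7.57 to 7.91) and Ccn1 (9.74 against 10.79 to 10.96).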

How the results depend on the processing

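The choices of lines described as added below were made after seeing the data; all other alternatives were fixed before the data were examined. Of 6937 values of named genes over the alternatives (196 results), 6715 kept their direction and their side of the threshold, 151 no longer passed, 10 newly passed, 61 that had not passed changed sign and 0 that had passed changed sign. Most values belong to results that had not passed (4824 in carcinoma against normal), so the pooled share says little about calls. The 151 losses all fall on results that had passed. Among these, 79 of 356 values were lost in hyperplasia against normal and 17 of 100 between the normal lines. For the sets apart from both normal lines, 45 of 400 were lost in adenoma and 6 of 400 in hyperplasia. Scaling moved the median of all probes by under 0.1 log2 units in each stage comparison. All the scalings are quantile normalized between arrays, which holds that median near 0 in advance. The small movement is therefore no test of the normalization. Dim signals limit most calls in hyperplasia: 19 of the 34 probes were above background in HpAF1 alone. The chip as a block was not run, since the files give no chips. Unless a sentence below says otherwise, the cause was not tested.

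With normexp scaling, 21 probes passed in hyperplasia and 9 between the normal lines. Without the detection filter, 52 passed in hyperplasia and 72 between carcinoma and hyperplasia; with detection on at least 4 arrays the counts were 0 and 7. That filter leaves out 20 of the 34 hyperplasia probes by construction, and what ended the other 14 calls was not tested. With the line as a random block, 1 probe passed in carcinoma against normal (Epha3), 256 in hyperplasia and 390 between carcinoma and hyperplasia. With the culture number as a further replicate block, these were 1 (Epha3), 217 and 325. With arrays as independent, which counts cultures as lines, 7, 780 and 1127 passed, and 4 in the trend. With only the 2 groups compared in the fit, 258 passed in hyperplasia, 2 in adenoma and 20 between carcinoma and hyperplasia. At an adjusted p under 0.10, 73 passed in hyperplasia, 119 between carcinoma and hyperplasia and 24 between the normal lines, and 1263 (hyperplasia) and 238 (adenoma) lay apart from both normal lines.

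Culture numbers pair part of the arrays: culture 1 and culture 2 deviated together in 10 of 10 pairs of NF2, NF3, CAF2, CAF3 and CAF4 (correlations 0.136 to 0.653) and in 2 of 18 pairs with another line above 0.1. Within these 5 lines, an added choice, 1 probe passed in carcinoma against normal with lines averaged and 4 with the replicate block. CAF2, CAF3 and CAF4 with the replicate block had 3 probes apart from both normal lines. Centring each chromosome of each line, also added, moved no count of genes by over 1.5 times. With the estimated correlation, 0 lists passed in carcinoma, 0 in hyperplasia and 0 in adenoma, and with fry 0, 0 and 0. With all probes of a gene averaged, 2 lists passed in hyperplasia.

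Leaving out each line in turn gave 0 to 1 probes in carcinoma against normal (1 without CAF1), 0 to 82 in hyperplasia (0 without NF3, 3 without NF2, 13 without CAF3, 16 without CAF4, 82 without CAF1), 20 to 186 between carcinoma and hyperplasia (20 without NF2, NF3 or CAF4, 27 without CAF3, 186 without CAF1), 0 to 16 between carcinoma and adenoma (16 without CAF1), and 0 in adenoma and in the trend. Lists numbered 2 to 5 in carcinoma (2 without CAF1, 5 without CAF2), 2 to 7 in hyperplasia (2 without NF2, 3 without NF3 or CAF2) and 3 to 10 in adenoma (3 without NF3). Leaving out each array gave 0 probes in carcinoma, adenoma, the trend and carcinoma against adenoma, 25 to 39 in hyperplasia and 28 to 61 between carcinoma and hyperplasia (28 without NF3 culture 1). Probes apart from both normal lines numbered 0 to 5 in carcinoma (0 without either CAF1 culture, 5 and 2 without NF3 culture 1 and 2), 253 to 870 in hyperplasia (294 and 253 without HpAF1 culture 1 and 2) and 50 to 186 in adenoma (50 and 52 without AdAF1 culture 1 and 2, 90 without either HpAF1 and 85 without either CAF1 culture). Among the carcinoma lines 775 to 2543 differed (820 and 775 without CAF1 culture 1 and 2), and between the normal lines 8 to 158 (158 and 43 without NF3 culture 1 and 2, 51 and 28 without NF2 culture 1 and 2, 8 without any HpAF1 or CAF1 array). Apart in single lines were 67 to 309 in CAF1, 75 to 338 in CAF2, 51 to 232 in CAF3 and 46 to 94 in CAF4.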

Other observations

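The tests of shared sets, chromosomes and splits in this part were chosen after the results were seen, as were the genes named as examples.

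AdAF1 and CAF1, from different stages, shared more of their departures from the normal lines than any other pair of lesion lines: 71 probes were higher and 18 lower in both, against 1.74 and 0.193 expected of independent sets, and 0 went opposite ways. Lrrc15, a membrane protein of activated fibroblasts, stood at 10.35 and 10.15 in them against 5.40 and 5.36 in the normal lines, and Rsad2 at 7.34 and 7.41 against 4.96 and 4.96. HpAF1 shared 53 higher and 24 lower probes with CAF1, and 44 and 21 with AdAF1, while HpAF1 and CAF2 departed in opposite directions in 23. All these sets share the normal lines, which raises overlaps. A handling batch of HpAF1, AdAF1 and CAF1, which cannot be told apart from the lines, could raise them too.

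In CAF1, Mbp, a myelin protein, and Ngfr, the low-affinity nerve growth factor receptor, made up 2 of the 2 tested Schwann cell and neural crest genes, both on the higher side (Fisher's exact test, adjusted p = 0.00311). Ngfr stood at 6.70 in CAF1 and at most at 5.04 in the other lines, while Mbp was also on the higher side in HpAF1 (7.70) and AdAF1 (7.14). In CAF4, Calr, a chaperone of the endoplasmic reticulum, stood at 14.76 against 11.20 to 11.57 in the other lines, and Hoxd10 at 8.78 against at most 4.88, beside the lower Hoxc6 and Hoxc9. In CAF2, the chemokine Cxcl12 stood at 4.82 and Igf2, a growth factor of fetal tissue, at 8.13, against 10.48 and 13.02 in NF2. Genes that 3 or more carcinoma lines shared were Eng, H2-T23, Lrrc15 and Ramp1 on the higher side and Epha3, Galnt9, Gldc, Sdk1, Serping1 and Tspyl3 on the lower side, although Tspyl3 was on the higher side in CAF1 (8.81).

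Genes that set a line apart were over-represented on single chromosomes in 9 of 240 tests (Fisher's exact test, adjusted). On the higher side these were chromosomes 6 (100 of 419 probes with a chromosome, where 23.0 were expected; adjusted p = 3.2e-36) and 18 (34 probes; adjusted p = 1.16e-08) in HpAF1, 14 in CAF2 (16 probes; adjusted p = 9.27e-06), and 1 in CAF3 (12 probes; adjusted p = 0.0236) and CAF4 (11 probes; adjusted p = 0.000159). On the lower side they were 11 (53 probes; adjusted p = 0.000622) and 13 (41 probes; adjusted p = 4.66e-11) in HpAF1, and 13 (10 probes; adjusted p = 0.00151) and 18 (20 probes; adjusted p = 1.12e-15) in CAF3. In NF3, medians of whole chromosomes differed between cultures of the line, with 0.46 and -0.10 for chromosome 8 and -0.08 and 0.47 for chromosome 10.

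The 6 normal and carcinoma lines can be split into 2 and 4 in 15 ways, which are too few for a share under 0.05. The real split gave 293 probes at an unadjusted p under 0.05, and 13 of the 15 splits, the real one included, gave as many; the highest of the others gave 1290. That split set CAF1 and CAF3 against the rest, and 0 probes passed the adjusted threshold in it. A count several times the real one can point to a structure of the lines, which was not tested. With CAF3 and CAF4 against the rest, 10 probes passed the adjusted threshold, where the real split gave 0.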
